A study of Mus musculus with 38 samples.

How the data were processed

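Hearts of 19 FVB/N mice were studied, labelled male and 12 weeks old, with or without a miR-133a transgene and after sham surgery or 1 week of TAC. Per the labels, each RNA came from coronal heart sections without the right ventricle, and each heart gave 1 polyadenylated RNA library and 1 library of RNA precipitated with Ago2 (RISC), so 38 libraries were used in 8 groups. Group and replicate number of each library came from the sample titles. Libraries were single-end and not strand-specific, so antisense transcripts could not be separated.

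The deposited values were raw read counts per gene symbol, 1 file of 23420 symbols per library. Per the submitters' processing notes, reads were aligned to mm10 with TopHat2 2.0.10 and Bowtie2 and counted with HTSeq, and the notes also named DESeq and edgeR. The gene models were the deposited mm10 annotation. Of the symbols 27 had been turned into dates, 2 of them occurred more than 1 time, and they held at most 0.0952% of a library's counts. They were left as they were. The whole-series tables held the same counts and were not used. The upper limit given for a count of 0 covers counting error only, while SD and SE also take in the spread between hearts. Reads had no molecular identifiers.

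Counts were analysed in R 4.3.3 with edgeR 4.0.16, in 1 fit for mRNA, 1 for RISC and 1 for both assays. Library sizes were scaled by TMM, genes were kept by filterByExpr, and robust quasi-likelihood tests with a Benjamini-Hochberg adjusted p under 0.05 called a gene. CPM are TMM-normalised counts per 1e6 counts, with SD. Fold changes are log2 with SE. The 13 comparisons were the transgene effect in sham and in TAC hearts, the TAC effect in each genotype and their interaction, each in mRNA and in RISC, the transgene effect on the RISC over mRNA ratio in sham and in TAC hearts, and that ratio in nontransgenic sham hearts. The choice of comparisons, tests, gene lists, named genes and first set of other settings was made before the data were examined.

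Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and p was adjusted over the lists of a comparison. The 28 lists held 645 entries, of which 641 matched a symbol. They were fetal and hypertrophy, extracellular matrix, sarcomere, calcium handling, potassium and pacemaker channels, beta-adrenergic signalling, reported miR-133 targets, microRNA pathway, smooth muscle and SRF, immediate-early and stress, endoplasmic reticulum stress, interferon response, cell cycle, ribosomal proteins, oxidative phosphorylation, fatty acid oxidation and glycolysis. The others were markers of cardiomyocytes, atria, fibroblasts, mural cells, endothelium, epicardium, macrophages, lymphocytes, erythroid cells, adipocytes and nerve. Membership rested on general knowledge, and each list count is also given with p adjusted over the list alone.

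Named genes were chosen by rule. It took the 6 largest and 6 smallest log2 fold changes among called genes with an average log2 CPM of at least 2. From each list with at least 2 called members it took the 2 with the smallest p, or 3 for the hypertrophy, matrix, channel and miR-133 target lists. It always took Mir133a-1, Mir133a-2, Mir133b, Mib1, Nppa, Nppb, Myh6, Myh7, Acta1, Kcnd2, Kcnip2, Ctgf, Col1a1 and Eif2c2. No fold change is given where a group had 0 counts.

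The other settings fixed at that time were RLE size factors, no low-count filter, only the groups compared, DESeq2 1.42.0, limma-voom with sample quality weights, a replicate block, and each library or heart left out in turn. For the lists they were the estimated correlation and fry. Chosen after seeing the data were Y-linked signal as a covariate, hearts with Y-linked signal alone, atrial transcripts as a covariate, a small noncoding RNA level as a covariate (the mean log2 CPM of Rnu12, Snord83b, Snora78 and Rnu11, mRNA only), the heart block with the precipitates of ntg TAC replicates 1 and 3 exchanged, and RISC without 2 libraries that stood apart. A heart had Y-linked signal where 4 Y-linked genes summed to at least 10 CPM. The atrial covariate is the log2 of the summed CPM of Myl4, Myl7, Sln and Mybphl. The mean of their log2 CPM was tried before it, and it gave 311 called genes for the transgene in sham RISC, 14 for the sham RISC over mRNA ratio and 43 for the TAC ratio.

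Each heart gave both assays, per the series text. Deviations from the group means of a heart's mRNA and RISC libraries had a median correlation of 0.0516 over 19 pairs, 6 of them above 0.1, and 9 libraries matched their own heart best. The mRNA libraries of ntg TAC replicates 1 and 3 had -0.201 and -0.175 with their own precipitates but 0.339 and 0.344 with each other's, as if the labels of 1 assay were crossed, which bears on the heart block and on the hearts left out of the ratio fits. The fit with heart as a block is given beside a ratio where it moved the count by over 1.5 times. The procedure was tested on simulated data, in which edgeR made 1.55 to 12.4% false calls. Tests of miR-133a seed sites in 3' untranslated regions were left out because no genome sequence was at hand.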

Results

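RNA was sequenced from the hearts of 19 FVB/N mice that carried a miR-133a transgene (TG133a, 11 hearts) or did not (ntg, 8 hearts). The mice had sham surgery or 1 week of transverse aortic constriction (TAC), which narrows the aorta and overloads the left ventricle with pressure. Groups held 3 ntg sham, 7 TG133a sham, 5 ntg TAC and 4 TG133a TAC hearts. Each heart gave 1 polyadenylated RNA library (mRNA) and 1 library of RNA bound to the microRNA effector protein Ago2 (RISC), 38 libraries in all. The total count per library was 6.35 to 14.5 M for mRNA and 2.90 to 11.8 M for RISC. Without Rn45s, a ribosomal RNA precursor that took at least 5.27% of mRNA and 45.8 to 59.0% of RISC counts, and the Lars2 locus, 5.83 to 12.9 M and 1.16 to 4.67 M counts remained.

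The precursor gene Mir133a-1 was read in 10 of 11 transgenic mRNA libraries, with 62 reads in total, and in 0 of 8 nontransgenic ones (two-sided Fisher exact p = 0.000119). The transgenic sham libraries held 54 of these reads and the transgenic TAC libraries 8. TG133a sham replicate 6 had none, and a count of 0 allows up to 3 reads. Its gene copy Mir133a-2 had 28 transgenic and 20 nontransgenic mRNA reads. Mib1, which spans Mir133a-1 on the opposite strand, did not pass the test for the transgene in sham hearts (log2 fold change -0.05 ± 0.11, adjusted p = 0.821, edgeR). All hearts were labelled male, but 6 of 19 had a Y-linked sum of at most 3.16 CPM and Xist, the RNA that silences an X chromosome, at 93.2 to 162 CPM in mRNA. The other hearts had at least 49.2 and at most 5.87 CPM. The 6 were 2 ntg sham, 3 ntg TAC and 1 TG133a TAC hearts, 5 of 8 nontransgenic against 1 of 11 transgenic (two-sided Fisher exact p = 0.0408).

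Transgenic and nontransgenic sham mRNA were compared to find what miR-133a changed in unstressed hearts. Akap5, an anchor of protein kinase A (mm10 chromosome 12, 76324891 to 76334151), rose from 2.35 ± 0.840 CPM (SD, n = 3) to 10.2 ± 0.963 CPM (SD, n = 7), with a log2 fold change 2.10 ± 0.23 (SE), edgeR adjusted p = 1.94e-06. Ctgf, a matricellular growth factor and reported miR-133 target, fell from 334 ± 15.8 CPM (SD, n = 3) to 90.5 ± 20.8 CPM (SD, n = 7), with a log2 fold change -1.88 ± 0.31 (SE), edgeR adjusted p = 0.000859. Nppb, the brain natriuretic peptide gene, fell by 1.79 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.00104). The kruppel-like factor Klf15 and adenylyl cyclase Adcy6, both reported targets, also fell (log2 fold changes -1.17 ± 0.16, adjusted p = 5.09e-05, and -0.78 ± 0.08, adjusted p = 1.14e-06, edgeR). So did Eif2c2, which encodes Ago2 itself (log2 fold change -0.55 ± 0.09 (SE), edgeR adjusted p = 0.000174).

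Immediate-early and stress genes and endoplasmic reticulum stress genes tended to be lower in transgenic sham hearts. Hspa1a, an inducible chaperone, averaged 35.8 ± 36.7 CPM (SD, n = 3) in ntg and 1.52 ± 0.393 CPM (SD, n = 7) in TG133a sham hearts (log2 fold change -4.52 ± 0.47 (SE), edgeR adjusted p = 1.10e-05), though reads of Hspa1a and its near-identical copy Hspa1b (-3.76) cannot be assigned with certainty. The nuclear receptor Nr4a3 and the transcription factor Klf4 fell as well (log2 fold changes -3.18 ± 0.27, adjusted p = 1.46e-07, and -1.12 ± 0.11, adjusted p = 5.79e-07, edgeR). Of 24 immediate-early and stress genes, 2 rose and 12 fell, 2 and 12 adjusted over the list alone (median log2 fold change -0.41, limma camera adjusted p = 1.23e-08, adjusted p = 0.00432 with an estimated correlation). Of 22 endoplasmic reticulum stress genes, 0 rose and 10 fell, 0 and 15 adjusted over the list alone (median log2 fold change -0.30, limma camera adjusted p = 1.78e-06, adjusted p = 0.0114 with an estimated correlation). Pdia6 and Xbp1 had log2 fold changes of -0.48 and -0.56. The largest falls also took in the glucocorticoid-responsive genes Fam107a (-2.90) and Zbtb16 (-2.67), and Xist (-5.74), which followed the hearts without Y-linked signal. Among the largest rises were Snord83b (4.15), the retinoic acid hydroxylase Cyp26b1 (2.69), Snai3 (2.21), Akap5, Nrep (1.77) and the lipase inhibitor Angptl4 (1.73).

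Of 40 reported miR-133 targets, 3 rose and 8 fell, 3 and 10 adjusted over the list alone (median log2 fold change -0.05, limma camera adjusted p = 0.131, adjusted p = 0.463 with an estimated correlation). Of 28 beta-adrenergic signalling genes, 1 rose and 8 fell, 2 and 10 adjusted over the list alone (median log2 fold change -0.17, limma camera adjusted p = 0.0276, adjusted p = 0.410 with an estimated correlation). Of 27 sarcomere genes, 0 rose and 7 fell, 0 and 9 adjusted over the list alone (median log2 fold change -0.13, limma camera adjusted p = 0.000273, adjusted p = 0.321 with an estimated correlation). Lmod2 (-0.52) and titin, Ttn (-0.56), were lower. Of 22 fetal and hypertrophy genes, 0 rose and 4 fell, 1 and 4 adjusted over the list alone (median log2 fold change -0.22, limma camera adjusted p = 0.0435, adjusted p = 0.823 with an estimated correlation). Of 21 potassium and pacemaker channel genes, 3 rose and 2 fell, 3 and 2 adjusted over the list alone (median log2 fold change 0.03, limma camera adjusted p = 0.837, adjusted p = 0.981 with an estimated correlation). The transient outward channel genes Kcnd2 (-0.24 ± 0.17, adjusted p = 0.377) and Kcnip2 (-0.04 ± 0.12, adjusted p = 0.878) did not pass the edgeR test. Of 34 cell-cycle genes, 1 rose and 0 fell, 0 and 0 adjusted over the list alone (median log2 fold change 0.73, limma camera adjusted p = 0.000102, adjusted p = 0.725 with an estimated correlation). Of 12 cardiomyocyte markers, 0 rose and 2 fell, 0 and 5 adjusted over the list alone (median log2 fold change -0.24, limma camera adjusted p = 0.00746, adjusted p = 0.418 with an estimated correlation). Of 4 lymphocyte markers, 2 rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 fold change 2.01, limma camera adjusted p = 0.0112, adjusted p = 0.275 with an estimated correlation). The B cell genes Cd79a and Cd79b were higher (2.24 and 1.85).

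In total 1493 of 13065 genes passed, 634 higher and 859 lower with the transgene. Only 1 of the 3 ntg sham hearts had Y-linked signal, and a fit of hearts with that signal alone called 162 genes, while the small noncoding RNA level as a covariate left 889. Without ntg sham replicate 1 or 3 the count was 906 or 883. On simulated counts of this design edgeR recovered 67.2% of 67 genes changed 1.5-fold and 97.0% of 67 changed 2-fold, among 12964 genes. All changed genes had an average log2 CPM of at least 2, and their spread followed the common trend. Recovery of lower or more variable genes was not tested.

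**Figure D1:**
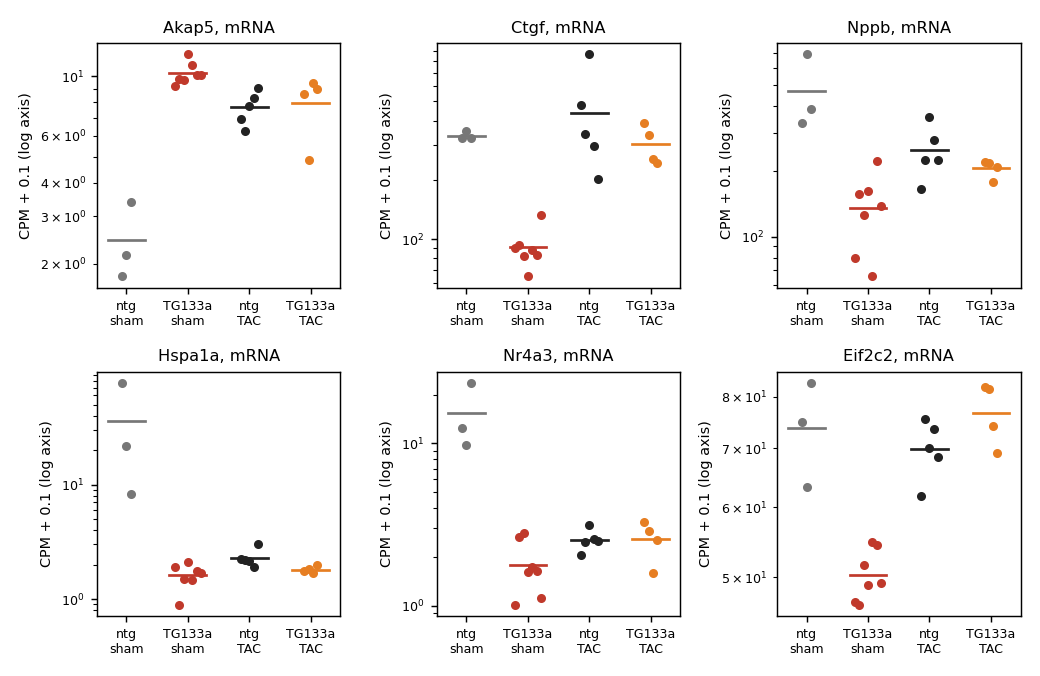
Normalised mRNA level (CPM plus 0.1, log axis) of 6 genes in each heart of the 4 groups, with lines at the group means. Ctgf, Nppb, Hspa1a and Nr4a3 were higher in all 3 ntg sham hearts than in all 7 TG133a sham hearts, and Akap5 was lower.

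Transgenic and nontransgenic TAC mRNA were compared to find what miR-133a changed under pressure overload. Cox5a, a subunit of cytochrome c oxidase, averaged 391 ± 112 CPM (SD, n = 5) in ntg TAC and 71.9 ± 12.9 CPM (SD, n = 4) in TG133a TAC hearts (log2 fold change -2.44 ± 0.34 (SE), edgeR adjusted p = 0.000574). Eno1, a glycolytic enolase, and Slc16a1, a lactate transporter, fell with the transgene (log2 fold changes -1.51 ± 0.20, adjusted p = 0.000196, and -1.13 ± 0.20, adjusted p = 0.00176, edgeR). So did Dnajb9, a chaperone of the endoplasmic reticulum (log2 fold change -2.16 ± 0.32 (SE), edgeR adjusted p = 0.000560). The proteoglycans Lum and Dcn rose (log2 fold changes 0.98 ± 0.20, adjusted p = 0.00440, and 0.45 ± 0.11, adjusted p = 0.00903, edgeR). Among the largest rises were those of the noncoding RNA Tug1 (1.20), the phosphatase Ptpn4 (1.20), Bbip1 (1.18) and Ndufb3 (1.08). Among the largest falls were those of the small nuclear RNA Rnu12 (-6.05), the small nucleolar RNAs Snord83b (-5.89) and Snora78 (-2.94), Tmem38b (-3.45) and the atrial gene Mybphl (-3.39).

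Of 23 glycolysis genes, 0 rose and 5 fell, 1 and 6 adjusted over the list alone (median log2 fold change -0.11, limma camera adjusted p = 0.0420, adjusted p = 0.721 with an estimated correlation). Of 40 ribosomal protein genes, 1 rose and 11 fell, 2 and 14 adjusted over the list alone (median log2 fold change -0.08, limma camera adjusted p = 0.0616, adjusted p = 0.970 with an estimated correlation). Rpl13 (-1.03) and Rps23 (-0.95) were lower. Of 62 oxidative phosphorylation genes, 1 rose and 7 fell, 1 and 7 adjusted over the list alone (median log2 fold change -0.11, limma camera adjusted p = 0.138, adjusted p = 0.995 with an estimated correlation). Of 55 extracellular matrix genes, 3 rose and 0 fell, 2 and 0 adjusted over the list alone (median log2 fold change 0.15, limma camera adjusted p = 0.0345, adjusted p = 0.970 with an estimated correlation). Of 20 microRNA pathway genes, 4 rose and 0 fell, 4 and 0 adjusted over the list alone (median log2 fold change 0.11, limma camera adjusted p = 0.0420, adjusted p = 0.721 with an estimated correlation), including Cnot1 of the deadenylase complex (0.52). Of 24 immediate-early and stress genes, 0 rose and 5 fell, 0 and 5 adjusted over the list alone (median log2 fold change -0.32, limma camera adjusted p = 0.0345, adjusted p = 0.721 with an estimated correlation). Fibroblast markers (3 rose and 0 fell of 12, 3 and 0 adjusted over the list alone) had a camera adjusted p = 0.0345, and adjusted p = 0.760 with an estimated correlation. Among reported miR-133 targets, 1 rose and 5 fell of 40 (1 and 5 adjusted over the list alone), and Ctgf (-0.52 ± 0.32, adjusted p = 0.312), Nppb (-0.28 ± 0.31, adjusted p = 0.614) and Eif2c2 (0.14 ± 0.08, adjusted p = 0.307) did not pass the edgeR test.

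In total 1684 of 13065 genes passed, 724 higher and 960 lower. This balance turned to 933 higher and 766 lower without ntg TAC replicate 1, and to 521 and 332 without TG133a TAC replicate 2, which left 853 genes. The mean log2 CPM of 4 small noncoding RNAs was 3.84 to 6.27 in the ntg TAC and 1.24 to 1.90 in the TG133a TAC libraries, with no overlap. In sham libraries it ran the other way, at 2.07 to 3.20 in ntg and 1.90 to 5.83 in TG133a (means 2.51 and 4.36). With that level as a covariate edgeR called 0 genes (1033 at an unadjusted p under 0.05), and without it DESeq2 called 1838 and limma-voom 2336. Because the level split the TAC groups without overlap, the count of 0 cannot tell removal of the effect from loss of power. Hearts with Y-linked signal alone gave 88.

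Pressure overload itself was measured by comparing TAC with sham mRNA in each genotype. Collagen and matricellular genes rose, as Col1a1 did from 128 ± 58.7 CPM (SD, n = 3) to 837 ± 443 CPM (SD, n = 5) without and from 153 ± 21.7 CPM (SD, n = 7) to 892 ± 255 CPM (SD, n = 4) with the transgene. Its log2 fold changes were 2.71 ± 0.43, adjusted p = 8.16e-05, and 2.55 ± 0.32, adjusted p = 7.73e-06 (edgeR). The beta-myosin gene Myh7 and skeletal actin gene Acta1, of the fetal programme, rose in nontransgenic hearts (log2 fold changes 0.81 ± 0.13, adjusted p = 2.12e-05, and 2.83 ± 0.49, adjusted p = 0.000157, edgeR) and in transgenic hearts (0.48 ± 0.11, adjusted p = 0.000621, and 1.48 ± 0.36, adjusted p = 0.00230). The calcium pump inhibitor Pln and the fatty acid transporter Cd36 fell in nontransgenic hearts (-1.98 ± 0.17, adjusted p = 1.45e-08, and -1.74 ± 0.12, adjusted p = 7.94e-10, edgeR). The channel gene Kcnd2 fell in nontransgenic hearts (-0.88 ± 0.18, adjusted p = 0.000319, edgeR) and its partner Kcnip2 in transgenic hearts (-0.50 ± 0.11, adjusted p = 0.000439). Neither passed the edgeR test for an interaction, so no difference between genotypes is shown. Nppb fell in nontransgenic hearts (-0.91 ± 0.33, adjusted p = 0.0281, edgeR), where its sham level was high.

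Of 55 extracellular matrix genes, 45 rose and 4 fell, 45 and 4 adjusted over the list alone (median log2 fold change 1.63, limma camera adjusted p = 1.09e-09, adjusted p = 0.567 with an estimated correlation) in nontransgenic hearts. Of the same list in transgenic hearts, 49 rose and 0 fell of 55 (50 and 1 adjusted over the list alone, camera adjusted p = 7.67e-21, adjusted p = 0.305 with an estimated correlation). Tenascin C, Tnc (4.36), Cilp (3.80) and Ltbp2 (3.59) were among them. Of 62 oxidative phosphorylation genes, 0 rose and 49 fell, 0 and 50 adjusted over the list alone (median log2 fold change -0.68, limma camera adjusted p = 8.98e-12, adjusted p = 0.567 with an estimated correlation) in nontransgenic hearts, and 0 rose and 58 fell of 62 in transgenic hearts (0 and 58, camera adjusted p = 3.31e-21, adjusted p = 0.305 with an estimated correlation). Of 35 fatty acid oxidation genes, 0 rose and 23 fell, 0 and 24 adjusted over the list alone (median log2 fold change -0.68, limma camera adjusted p = 1.34e-07, adjusted p = 0.567 with an estimated correlation). With the transgene 1 rose and 30 fell of 35 (1 and 30, camera adjusted p = 1.90e-08, adjusted p = 0.462 with an estimated correlation). Of 34 cell-cycle genes, 31 rose and 1 fell, 31 and 1 adjusted over the list alone (median log2 fold change 1.91, limma camera adjusted p = 1.09e-09, adjusted p = 0.567 with an estimated correlation), with the mitotic activator Cdc20 at 2.95, and 24 rose and 1 fell of 34 with the transgene (24 and 1, camera adjusted p = 2.63e-05, adjusted p = 0.638 with an estimated correlation).

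The list values that follow are for nontransgenic hearts unless the transgene is named. Camera called 12 of 28 lists in nontransgenic and 9 of 28 in transgenic hearts, so a list given for nontransgenic hearts alone need not have changed in both. Of 22 fetal and hypertrophy genes, 13 rose and 1 fell, 13 and 1 adjusted over the list alone (median log2 fold change 0.71, limma camera adjusted p = 0.00222, adjusted p = 0.591 with an estimated correlation). In transgenic hearts 19 rose and 1 fell of 22 (19 and 1, camera adjusted p = 1.52e-07, adjusted p = 0.305 with an estimated correlation). Of 15 macrophage markers, 12 rose and 0 fell, 12 and 0 adjusted over the list alone (median log2 fold change 0.58, limma camera adjusted p = 0.00167, adjusted p = 0.567 with an estimated correlation), with the growth factor receptor Csf1r (0.79) and complement gene C1qb (0.72) higher, and 14 rose and 0 fell of 15 with the transgene (14 and 0, camera adjusted p = 2.63e-05, adjusted p = 0.305 with an estimated correlation). Of 23 smooth muscle and SRF genes, 12 rose and 1 fell, 12 and 1 adjusted over the list alone (median log2 fold change 0.69, limma camera adjusted p = 0.00173, adjusted p = 0.567 with an estimated correlation). Of 20 interferon response genes, 9 rose and 0 fell, 9 and 0 adjusted over the list alone (median log2 fold change 0.57, limma camera adjusted p = 0.0141, adjusted p = 0.591 with an estimated correlation). Of 40 ribosomal protein genes, 1 rose and 20 fell, 1 and 20 adjusted over the list alone (median log2 fold change -0.29, limma camera adjusted p = 0.00104, adjusted p = 0.627 with an estimated correlation). With the transgene 1 rose and 33 fell of 40 (1 and 34, camera adjusted p = 2.55e-06, adjusted p = 0.634 with an estimated correlation). Of 22 endoplasmic reticulum stress genes, 1 rose and 11 fell, 1 and 11 adjusted over the list alone (median log2 fold change -0.21, limma camera adjusted p = 0.0141, adjusted p = 0.567 with an estimated correlation) in nontransgenic hearts. As a list these genes stood higher in ntg than in TG133a sham hearts. Of 12 cardiomyocyte markers, 0 rose and 8 fell, 0 and 8 adjusted over the list alone (median log2 fold change -0.45, limma camera adjusted p = 0.0256, adjusted p = 0.567 with an estimated correlation), and 2 rose and 6 fell of 12 with the transgene (2 and 6, camera adjusted p = 0.173, adjusted p = 0.652 with an estimated correlation). Of 12 fibroblast markers, 6 rose and 2 fell, 7 and 2 adjusted over the list alone (median log2 fold change 0.32, limma camera adjusted p = 0.144, adjusted p = 0.627 with an estimated correlation), and 9 rose and 0 fell of 12 with the transgene (11 and 0, camera adjusted p = 0.000125, adjusted p = 0.305 with an estimated correlation). Of 12 mural cell markers, 4 rose and 2 fell, 4 and 2 adjusted over the list alone (median log2 fold change 0.45, limma camera adjusted p = 0.144, adjusted p = 0.591 with an estimated correlation), with Notch3 at 1.15. Of 12 endothelial markers, 5 rose and 2 fell, 5 and 2 adjusted over the list alone (median log2 fold change 0.16, limma camera adjusted p = 0.378, adjusted p = 0.764 with an estimated correlation). Of 29 calcium handling genes, 5 rose and 13 fell, 5 and 13 adjusted over the list alone (median log2 fold change -0.14, limma camera adjusted p = 0.0712, adjusted p = 0.567 with an estimated correlation). Their mean had the other sign (0.12). Of 6 nerve markers 1 rose and 1 fell, of 3 erythroid and 6 adipocyte markers 0 passed, and of 7 epicardial markers 1 rose, with the same counts adjusted over each list alone. Their limma camera adjusted p was 0.865, 0.837, 0.785 and 0.616. Of 7 atrial markers, 6 rose and 0 fell, 7 and 0 adjusted over the list alone (median log2 fold change 4.12, limma camera adjusted p = 0.0430, adjusted p = 0.591 with an estimated correlation). The atrial light chain Myl7 stood at 45.2 to 1428 CPM in ntg TAC against 1.10 to 2.74 CPM in ntg sham mRNA. In transgenic mRNA the summed level of the 4 transcripts of the atrial covariate averaged 59.7 ± 106 CPM (SD, n = 7) in sham and 104 ± 102 CPM (SD, n = 4) in TAC hearts. In nontransgenic mRNA it averaged 3.83 ± 0.970 CPM (SD, n = 3) and 958 ± 1175 CPM (SD, n = 5).

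These comparisons called 7147 genes in nontransgenic hearts (3560 higher, 3587 lower) and 7493 in transgenic hearts (3593 and 3900) of 13065. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Spearman correlation of 0.640, and 2206 genes rose and 2318 fell in both. Independent lists would share 979 and 1071. In transgenic hearts 3981 genes passed with the small noncoding RNA level as a covariate, and in nontransgenic hearts 2201 passed where Y-linked signal was required. Sham and TAC hearts carried animal numbers from separate ranges, so surgery and cohort cannot be told apart.

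**Figure D2:**
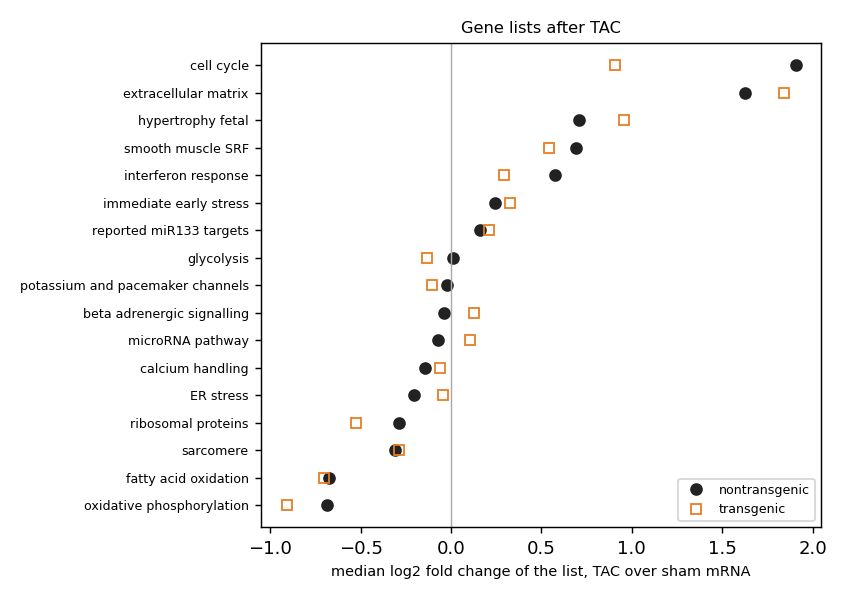
Median log2 fold change, TAC over sham mRNA, of each of 17 gene lists (vertical axis) in nontransgenic (filled circles) and transgenic hearts (open squares). Extracellular matrix genes had medians of 1.63 and 1.84, and oxidative phosphorylation genes of -0.68 and -0.91.

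The interaction asked which TAC responses differed between genotypes. Ctgf and Nppb had more positive TAC responses with the transgene (log2 fold change 1.36 ± 0.45 (SE), edgeR adjusted p = 0.0406, and 1.51 ± 0.44, adjusted p = 0.0229), as had Eif2c2 (0.68 ± 0.12, adjusted p = 0.000532, edgeR). Akap5 had a more negative one (-2.05 ± 0.29, adjusted p = 5.82e-05, edgeR), and it stood at 7.55 ± 1.09 CPM (SD, n = 5) and 7.84 ± 2.07 CPM (SD, n = 4) after TAC. The stress genes Hspa1a and Nr4a3 and the glucocorticoid-responsive genes Fam107a and Zbtb16 had positive interactions of 4.17, 3.19, 3.18 and 3.07. These genes, like Ctgf, Nppb and Eif2c2, were lower with the transgene in sham hearts, and the interaction includes that sham difference. Rnu12 (-10.28), Snord83b (-10.04) and Myl4 (-7.28) were among the most negative. Of 20 microRNA pathway genes 6 had positive and 0 negative interactions (6 and 0 adjusted over the list alone, camera adjusted p = 0.0295, adjusted p = 0.501 with an estimated correlation). Cell-cycle genes had 0 positive and 4 negative of 34 (0 and 3, median -0.79, camera adjusted p = 0.00153, adjusted p = 0.916 with an estimated correlation). Lymphocyte markers had 0 and 4 of 4 (0 and 4, camera adjusted p = 0.0336, adjusted p = 0.501 with an estimated correlation). Nppa, Myh7, Acta1, Kcnd2 and Col1a1 did not pass the edgeR test (adjusted p = 0.165, 0.163, 0.108, 0.120 and 0.858). In total 2717 of 13065 genes passed, 1263 positive and 1454 negative, a balance that turned to 1147 and 940 without TG133a TAC replicate 2, 1330 and 1105 without TG133a sham replicate 2 and 1447 and 1442 without ntg TAC replicate 1. With the small noncoding RNA level as a covariate 58 passed, and 347 in hearts with Y-linked signal alone.

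In Ago2 precipitates of sham hearts, the comparison asked which bound transcripts differed with the transgene. Ctgf fell from 350.2 ± 124 CPM (SD, n = 3) to 52.9 ± 16.1 CPM (SD, n = 7), with a log2 fold change -2.73 ± 0.41 (SE), edgeR adjusted p = 0.000614. Akap5 rose (log2 fold change 2.87 ± 0.47 (SE), edgeR adjusted p = 5.06e-05). The myosin genes Myh6 and Myh7 fell (log2 fold changes -0.71 ± 0.13, adjusted p = 0.000110, and -0.78 ± 0.11, adjusted p = 3.85e-06, edgeR), as did Nppb (-1.60 ± 0.26, adjusted p = 0.000834) and Kcnd2 (-0.96 ± 0.25, adjusted p = 0.0127). The reported target Casp9 and pacemaker channel Hcn4 were higher (1.21 ± 0.27, adjusted p = 0.00254, and 1.56 ± 0.40, adjusted p = 0.00829, edgeR). The chaperone Hspa5 was lower (-1.14 ± 0.16, adjusted p = 3.07e-06, edgeR), and of 22 endoplasmic reticulum stress genes, 0 rose and 7 fell, 0 and 14 adjusted over the list alone (median log2 fold change -0.55, limma camera adjusted p = 1.46e-10, adjusted p = 0.00252 with an estimated correlation). Of 25 immediate-early and stress genes, 0 rose and 9 fell, 1 and 11 adjusted over the list alone (median log2 fold change -0.50, limma camera adjusted p = 9.32e-07, adjusted p = 0.173 with an estimated correlation). Of 54 extracellular matrix genes, 0 rose and 6 fell, 0 and 6 adjusted over the list alone (median log2 fold change -0.28, limma camera adjusted p = 5.76e-05, adjusted p = 0.506 with an estimated correlation). Among reported miR-133 targets 3 rose and 4 fell of 40 (6 and 4 adjusted over the list alone, median 0.04 but mean -0.02, camera adjusted p = 0.955). Among the largest changes were those of Cyp26b1 (3.19), Bcl11b (2.92) and the kinase gene Map3k6 (-2.74).

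In total 898 of 12789 genes passed, 426 higher and 472 lower, and 197 genes fell and 133 rose in both assays of the same hearts, where independent lists would share 32.4 and 20.8. With atrial transcripts as a covariate 343 passed, with Y-linked signal as one 553, and 118 in hearts with that signal alone. Without ntg sham replicate 1 or 2 the count was 511 or 432.

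In precipitates of TAC hearts edgeR called 0 of 12789 genes for the transgene. At an unadjusted p under 0.05 it had 511, while DESeq2 and limma-voom also called 0 (595 and 655 unadjusted). Ctgf had a log2 fold change of -0.16 ± 0.42 (SE), Nppb of 0.19 ± 0.27, Myh7 of -0.10 ± 0.11 and Eif2c2 of 0.00 ± 0.17 (n = 4 and 5). Of 5 adipocyte markers 0 passed, and 3 fell when adjusted over the list alone (median -1.90, limma camera adjusted p = 3.35e-05, adjusted p = 0.240 with an estimated correlation). Extracellular matrix genes had a median of -0.16 (camera adjusted p = 0.00700, adjusted p = 0.764 with an estimated correlation). On simulated counts of this design edgeR recovered 55.2% of 67 genes changed 2-fold and 98.5% of 66 changed 4-fold, among 12298 genes. All changed genes had an average log2 CPM of at least 2, and their spread followed the common trend. Recovery of lower or more variable genes was not tested.

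Ago2 precipitates differed between TAC and sham hearts in both genotypes, and surgery and cohort cannot be told apart here either. The Lars2 locus took 10.0 to 16.6% of counts in sham and 4.50 to 7.61% in TAC precipitates, against 2.10 to 3.32% and 1.02 to 1.97% in mRNA. Fatty acid genes fell, Hadhb, of mitochondrial beta-oxidation, by 1.88 ± 0.15 on the log2 scale without the transgene (SE, edgeR adjusted p = 7.18e-13). Col1a1 rose (log2 fold changes 1.73 ± 0.25, adjusted p = 2.98e-05 without and 1.41 ± 0.19, adjusted p = 4.61e-05 with the transgene, edgeR), as did Nmrk2, an NAD synthesis kinase (1.80 ± 0.25, adjusted p = 2.62e-07, and 1.89 ± 0.19, adjusted p = 3.21e-10). Eif2c2 rose (0.89 ± 0.19, adjusted p = 0.000620, and 0.62 ± 0.15, adjusted p = 0.00489, edgeR). Of 35 fatty acid oxidation genes, 0 rose and 25 fell, 0 and 30 adjusted over the list alone (median log2 fold change -0.89, limma camera adjusted p = 2.09e-22, adjusted p = 0.0664 with an estimated correlation) without the transgene. Of 22 endoplasmic reticulum stress genes, 0 rose and 16 fell, 0 and 17 adjusted over the list alone (median log2 fold change -0.73, limma camera adjusted p = 4.09e-11, adjusted p = 0.00231 with an estimated correlation). Of 33 cell-cycle genes, 18 rose and 0 fell, 22 and 0 adjusted over the list alone (median log2 fold change 2.05, limma camera adjusted p = 5.80e-10, adjusted p = 0.0664 with an estimated correlation). With the transgene, 14 rose and 0 fell of 21 fetal and hypertrophy genes (14 and 1 adjusted over the list alone, camera adjusted p = 1.02e-14, adjusted p = 0.0587 with an estimated correlation) and 0 rose and 38 fell of 62 oxidative phosphorylation genes (0 and 52, camera adjusted p = 3.58e-27, adjusted p = 0.0731 with an estimated correlation).

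The nuclear noncoding RNA Neat1 rose in RISC from 156 ± 15.5 CPM (SD, n = 3) to 2268 ± 414 CPM (SD, n = 5) without the transgene, while it averaged 1303 ± 183 CPM and 1620 ± 196 CPM in mRNA of the same hearts. Chga, which encodes the secretory granule protein chromogranin A, averaged 13 ± 6.85 CPM (SD, n = 3) and 16.2 ± 14.9 CPM (SD, n = 7) in sham RISC and at most 0.246 CPM in any TAC RISC library. Its highest value in an mRNA library was 0.465 CPM.

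In total 2676 of 12789 genes passed without the transgene (1420 higher, 1256 lower) and 1578 with it (920 and 658). Without TG133a TAC replicate 2 the latter count was 904, and the former was 443 in hearts with Y-linked signal alone. The interaction called 261 genes, 142 positive and 119 negative, with Ctgf (2.56 ± 0.59, adjusted p = 0.0353), Nppb (1.79 ± 0.38, adjusted p = 0.0163), Myh7 (0.68 ± 0.16, adjusted p = 0.0134) and Akap5 (-3.16 ± 0.59, adjusted p = 0.000957) among them (edgeR). DESeq2 called 409, limma-voom 407, and hearts with Y-linked signal gave 15. Of 22 endoplasmic reticulum stress genes 3 had positive and 0 negative interactions, 5 and 0 adjusted over the list alone (median 0.59, camera adjusted p = 9.54e-08, adjusted p = 0.0114 with an estimated correlation). Immediate-early and stress genes had 5 and 0 of 25, 7 and 0 (camera adjusted p = 0.000100, adjusted p = 0.415 with an estimated correlation), and fetal and hypertrophy genes 3 and 0 of 21, 3 and 0 (camera adjusted p = 0.00107, adjusted p = 0.415 with an estimated correlation). Cell-cycle genes had 0 and 0 of 33 with 0 and 5 adjusted over the list alone (median -0.64, camera adjusted p = 0.00160, adjusted p = 0.415 with an estimated correlation). Camera called 7 lists of 27 in this interaction, 1 of them with an estimated correlation.

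**Figure D3:**
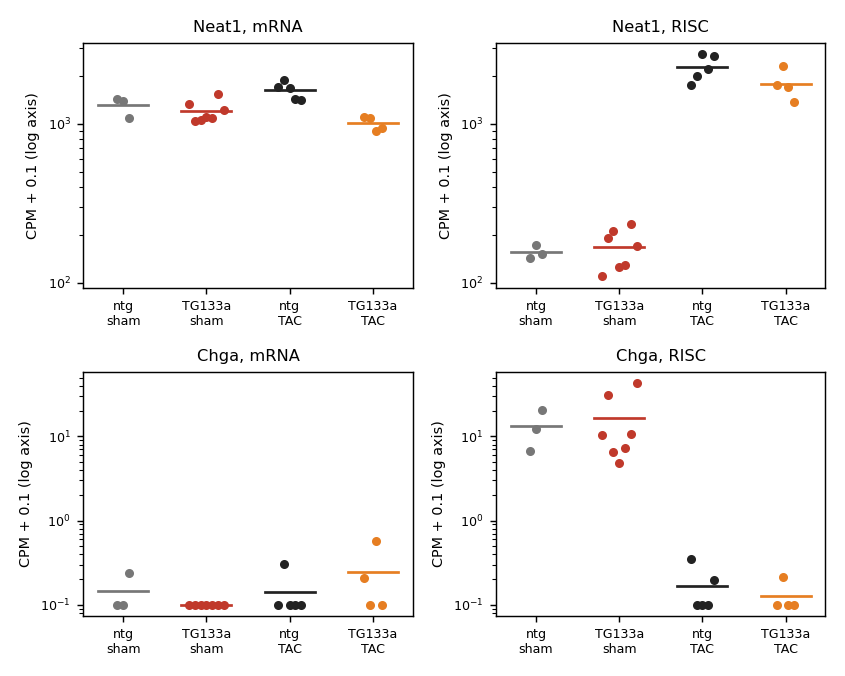
Normalised level (CPM plus 0.1, log axis) of Neat1 and Chga in each mRNA and RISC library of the 4 groups, with lines at the group means. All 9 TAC precipitates lay above all 10 sham precipitates for Neat1 and below them for Chga, which stayed under 1 CPM in mRNA.

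The RISC over mRNA ratio asked which transcripts were bound to Ago2 beyond their abundance. With the transgene in sham hearts Eif2c2 (0.85 ± 0.22, adjusted p = 0.0370) and Tnrc6c, a partner of Ago proteins (0.71 ± 0.15, adjusted p = 0.00879), had higher ratios (log2, edgeR). So had the reported targets Prdm16, a regulator of brown fat (0.91 ± 0.21, adjusted p = 0.0191), and Adcy6 (0.70 ± 0.17, adjusted p = 0.0240). Myh7 had a lower one (-0.78 ± 0.17, adjusted p = 0.0112, edgeR). Eif2c2 and Adcy6 were also lower in transgenic sham mRNA, so their higher ratios need not mean more binding to Ago2. Of 40 reported targets 2 had a higher and 0 a lower ratio, 5 and 0 adjusted over the list alone (median 0.07, limma camera adjusted p = 0.447). Ctgf did not pass (-0.83 ± 0.55, adjusted p = 0.544, edgeR). Among the largest ratio changes were those of Hist2h2bb (2.18) and Tcirg1 (2.16), and among the smallest those of Fasn (-1.89) and C5ar2 (-1.89). In total 176 of 13580 genes passed, 140 higher and 36 lower, against 95 with heart as a block and 198 with that block after the precipitates of ntg TAC replicates 1 and 3 were exchanged. The share of higher calls depended on scaling and tool, with 80 higher and 46 lower under RLE size factors and 218 and 165 by DESeq2. The count was 11 without ntg sham replicate 1, 79 without replicate 2, 36 without replicate 3, 98 without TG133a sham replicate 1, 105 without replicate 5, 22 with Y-linked signal and 17 with atrial transcripts as a covariate. With the sham groups alone 46 passed, and DESeq2 called 383 in total.

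In TAC hearts Cox5a and Uqcrfs1, of the respiratory chain, had higher ratios with the transgene (log2 2.35 ± 0.38, adjusted p = 0.00150, and 1.00 ± 0.21, adjusted p = 0.0105, edgeR), as had Rnu12 (6.18) and Snord83b (5.50), which had low mRNA levels in TG133a TAC hearts. Cox5a was also lower in TG133a TAC mRNA, and edgeR called 0 genes for the transgene in TAC RISC. A higher ratio here thus need not mean more binding to Ago2. The small noncoding RNA covariate was not applied to the ratio. S100a13 (-2.09), Bbip1 (-1.81) and Clk4 (-1.46) had lower ones. Of 62 oxidative phosphorylation genes 3 had a higher and 0 a lower ratio, 13 and 1 adjusted over the list alone (camera adjusted p = 1.81e-05, adjusted p = 0.696 with an estimated correlation). Of 40 reported targets 0 passed (edgeR, median 0.08). In total 66 of 13580 genes passed, 63 higher and 3 lower, while DESeq2 called 106 and limma-voom 10. The count was 9 without ntg TAC replicate 1, 42 without replicate 2, 100 without replicate 3 and 37 without replicate 4, and 36, 38, 24 and 29 without TG133a TAC replicates 1 to 4.

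In nontransgenic sham hearts the ratio separated long from short transcripts. The adaptor Tnrc6b and its paralog Tnrc6a were enriched with Ago2 (log2 ratios 2.18 ± 0.15, adjusted p = 3.56e-17, and 1.75 ± 0.14, adjusted p = 2.20e-15, edgeR), as were the miR-133 target Sp1 (1.84 ± 0.16, adjusted p = 3.25e-14) and Mib1 (1.92 ± 0.18, adjusted p = 1.57e-12). Troponin C, Tnnc1, and the complex I subunit Ndufa2 were depleted (-2.96 ± 0.15, adjusted p = 3.25e-22, and -3.93 ± 0.20, adjusted p = 4.80e-22, edgeR). Of 20 microRNA pathway genes 14 had a higher and 1 a lower ratio, 14 and 1 adjusted over the list alone (camera adjusted p = 1.81e-05, adjusted p = 0.0327 with an estimated correlation). All 40 ribosomal protein genes had lower ratios, 0 and 40 adjusted over the list alone (median -2.48, camera adjusted p = 1.97e-51, adjusted p = 0.00345 with an estimated correlation). Oxidative phosphorylation genes had 0 higher and 57 lower of 62, 0 and 57 adjusted over the list alone (camera adjusted p = 1.33e-51, adjusted p = 0.0179 with an estimated correlation), and sarcomere genes 3 and 20 of 27, 3 and 21 (camera adjusted p = 3.95e-10, adjusted p = 0.0324 with an estimated correlation). Across 13559 genes the ratio had a Spearman correlation of 0.503 with transcript length, with medians of -1.84 for transcripts under 1000 bases and 0.66 for those over 5000. The gene and list tests above did not adjust for length, so binding to Ago2 cannot be told apart from length here. In total 6807 of 13580 genes passed, 3253 higher and 3554 lower, and 3253 passed in hearts with Y-linked signal alone, which leave 1 nontransgenic sham heart.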

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

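The test of sex for the opposite transgene effects and the splits of the samples were planned before their results were seen. Every other test of an explanation below was chosen after the result was seen.

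Transgene effects in mRNA tended to run in opposite directions in sham and TAC hearts. Across 13065 genes, which are not independent replicates, the 2 sets of log2 fold changes had a Spearman correlation of -0.252, with 197 genes called in opposite directions against 94.2 expected, and 13 rising and 24 falling in both. Taking a trend on transcript length from each set left -0.223, which argues against length as the whole cause. Y-linked signal as a covariate left -0.202. Hearts without that signal were 2 of 3 ntg and 0 of 7 TG133a sham hearts, and 3 of 5 ntg and 1 of 4 TG133a TAC hearts. A sex effect shared by both surgeries would push both transgene effects the same way, so this imbalance, rather than the fit, argues against it. The small noncoding RNA level differed in opposite directions, higher with the transgene in sham and lower in TAC hearts. That level as a covariate left -0.287, against -0.252 without it. This fit held a common slope for all groups, while the level differed in opposite directions. An error in a gene's slope thus moves its 2 adjusted effects in opposite directions. For that reason the -0.287 cannot decide whether the level drives the opposite directions. Slopes on that level within the sham groups had a correlation of -0.480 with the transgene effect in TAC hearts, so unequal recovery of short RNAs may contribute to the TAC effect, although slopes within the TAC groups had only 0.0466 with those within the sham groups. For that reason the 0.0406 between the TAC slopes and the sham effect decides nothing. With the transgene effect in sham hearts the sham slopes had 0.183 (0.140 to 0.212 with 1 sham library left out of the slope), which leaves the sham side open. A transgene effect that differs after pressure overload stays open as an untested biological explanation, as does the separate origin of sham and TAC animals.

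Stress-responsive genes were high in nontransgenic sham hearts. Of the immediate-early and endoplasmic reticulum stress genes 22 fell in transgenic sham mRNA, with a median log2 fold change of -0.59 (quartiles -1.06 and -0.41). The median was -0.62 with Y-linked signal as a covariate (quartiles -1.01 and -0.42) and -0.63 with the small noncoding RNA level (-1.08 and -0.42), and 17 and 16 genes still passed. Sham groups alone with the small noncoding RNA level gave -0.61 (-1.13 and -0.40), with 13 genes passing. These values argue against sex and against short RNA recovery as the whole cause. In RISC 13 of the 22 fell, but in the same sham hearts the genes were chosen from, so this is not independent support. In TAC mRNA 2 of them fell with the transgene. With TAC 16 fell in nontransgenic hearts, a comparison that shares the 3 sham hearts the genes were chosen from. A transgene effect seen without overload, or the state of those 3 hearts at collection, could each give this pattern, and no test here separated them.

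RNAs with large TAC differences in the immunoprecipitates included nuclear and endocrine ones. Of 117 RNAs at least 4-fold different in both genotypes 108 were higher after TAC, and the 78 of the 117 that were also tested in mRNA had a median change there of 0.34 (log2, SD 0.90) against 2.93 in RISC for the same 78, which argues against the same change in heart RNA for the set. Their choice by RISC values raises the RISC median, and 22 of the 78 passed in mRNA in the same direction in both genotypes. Chromogranin and insulin transcripts, chosen after their values were seen, summed to 13.7 to 117 CPM in sham RISC, 0.124 to 11.0 CPM in TAC RISC and at most 1.77 CPM in any mRNA library, with both of these maxima in TG133a TAC replicate 3. Chromogranin with insulin transcripts had a Spearman correlation of 0.818 across 10 sham immunoprecipitates (permutation p = 0.00564) and a Pearson r of 0.895 (permutation p = 0.00115), 0.633 without the 2 farthest samples and 0.901 within the 7 transgenic sham ones, so 1 outside source of these RNAs may be a candidate, though the TAC maximum means that it need not be limited to sham precipitates. Whether the nuclear RNAs differed because of the surgery or because sham and TAC precipitates were made apart was not tested.

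Chance was examined by refitting other splits of the same samples. In mRNA it can be excluded for the transgene in sham hearts (1 of 100 splits as large, 1493 genes against 82 at most in another), the transgene in TAC hearts (1 of 100, 1684 against 454), TAC without the transgene (1 of 56, 7147 against 3775) and TAC with it (1 of 100, 7493 against 2058). In RISC it can be excluded for the transgene in sham hearts (1 of 100, 898 against 8), TAC without the transgene (1 of 56, 2676 against 239) and TAC with it (1 of 100, 1578 against 42). For the RISC interaction 1 of 100 splits was as large (261 against 234). Those splits moved the genotype in sham and in TAC hearts, which also removes the transgene effect in sham hearts. They thus cannot exclude chance for the interaction alone. Other settings gave RISC interaction counts under 234, among them 144 with the replicate block and 175 without ntg TAC replicate 5, and no splits were refitted there. For the transgene in TAC RISC edgeR called 0 genes (511 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom), so all 100 of 100 splits were as large by construction (15 at most in another) and this count tests nothing. For the RISC over mRNA ratio 1 of 60 splits was as large in sham (176 against 9) and in TAC hearts (66 against 33). Both assays of a heart moved together in these splits, so they cannot exclude chance for the ratio alone. Other settings gave TAC ratio counts under 33, among them 9 without ntg TAC replicate 1 and 10 by limma-voom, and no splits were refitted there. The 10 splits of nontransgenic sham libraries are too few for a share under 0.05 (6807 against 2).

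Of 68 sets of a gene and a group 5 had a library far from the others, and chance gives about 1 in 20. Ctgf stood at 133 CPM in TG133a sham mRNA replicate 7 (mean of the others 83.4), Eif2c2 at 198 CPM in TG133a sham RISC replicate 1 (96.7) and Kcnd2 at 30.9 CPM in TG133a sham mRNA replicate 5 (23.7). Kcnip2 stood at 119 CPM in TG133a TAC RISC replicate 1 (129) and Myh7 at 1299 CPM in TG133a TAC RISC replicate 2 (1106). The TAC response differed between genotypes, by the edgeR interaction, for Ctgf (1.36), Eif2c2 (0.68) and Nppb (1.51) in mRNA and for Ctgf (2.56), Myh7 (0.68) and Nppb (1.79) in RISC.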

How the results depend on the processing

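The covariates, the restriction to hearts with Y-linked signal, the exchanged heart block and the fit without 2 RISC libraries were chosen after the data were seen. Of the named genes' values 3616 kept their side of the threshold under the settings fixed in advance, and their direction where they passed. Of the rest 185 no longer passed, 24 newly passed and 0 turned, and leaving out libraries gave 6153, 436, 17 and 0. The settings added later gave 2198, 523, 9 and 12. A turn was counted only where a value passed with the main or the other setting, so values that passed with neither may have changed sign uncounted. Where counts below moved, the cause was not tested, apart from fewer samples in the restriction and left-out fits.

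Hearts with Y-linked signal alone gave 162 and 88 genes for the transgene in sham and TAC mRNA, 2201 for TAC without the transgene and 347 for the interaction. In RISC they gave 118, 1, 443 and 15. For the ratio they gave 0 and 0 by edgeR (924 and 733 at an unadjusted p under 0.05) where DESeq2 on all hearts gave 383 and 106, and 3253 in nontransgenic sham hearts, where 1 heart is assumed to vary like the other groups. The small noncoding RNA covariate gave 889 and 0 (1033 unadjusted) for the transgene in sham and TAC mRNA, 3981 for TAC with the transgene and 58 for the interaction. Y-linked signal as a covariate gave 553 in sham RISC and 22 for the sham ratio. Atrial transcripts as a covariate gave 343 in sham RISC and 17 for the sham ratio. The RISC interaction had 409 genes with DESeq2 and 407 with limma-voom. The sham ratio had 46 with its groups alone and 383 with DESeq2, the TAC ratio 106 with DESeq2 and 10 with limma-voom. Of 104 list calls 10 held with an estimated correlation and fry made 101.

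With replicate number as a block (replicate block) the RISC interaction had 144 genes, and with heart as a block the sham ratio had 95 and the TAC ratio 59. With the precipitates of ntg TAC replicates 1 and 3 exchanged, a pairing picked by its higher correlation in the same data, the heart block gave 198 and 88. The blocks moved no other count by over 1.5 times. Across groups same-numbered libraries shared only a number, since 3 of 22 mRNA and 0 of 22 RISC pairs had a correlation above 0.1.

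With each library or heart left out, mRNA counts ranged over 883 to 1541 and 853 to 1816 for the transgene in sham and TAC hearts, 5793 to 7410 and 6675 to 7344 for TAC without and with it, and 2005 to 2889 for the interaction. RISC counts ranged over 432 to 914 and 0 to 0 (edgeR, 360 to 656 unadjusted), 1928 to 2618 and 904 to 1557, and 175 to 282. Ratio counts ranged over 11 to 202 in sham, 9 to 100 in TAC and 5625 to 5775 in nontransgenic sham hearts.

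By that count log2 fold changes turned for Xist in sham mRNA (1.05) and Car3 in sham RISC (0.56) and in the nontransgenic sham ratio (-0.38) with Y-linked signal required. With the atrial covariate, which holds Sln and Myl7, those genes turned for TAC without the transgene in mRNA (-0.060 and -0.19), as did Lrrn4 in the nontransgenic sham ratio (-0.019). With the small noncoding RNA covariate Rnu12 turned in TAC mRNA (0.51), for TAC with the transgene (1.82) and in the interaction (0.39), Tmem38b in TAC mRNA (0.0061) and the interaction (0.050), and Snora7a in the interaction (1.17).

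Planned tests of genes with miR-133a sites, by site class, estimated correlation and matched background, were not run because no genome was at hand. Depth limits the RISC libraries most, at 1.16 M counts without Rn45s and Lars2 in the shallowest.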

Other observations

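Malat1, a nuclear noncoding RNA named after its values were seen, averaged 650.1 ± 67.8 CPM (SD, n = 3) and 650.4 ± 247 CPM (SD, n = 7) in sham RISC and 6492 ± 2057 CPM (SD, n = 5) and 4831 ± 280.0 CPM (SD, n = 4) in TAC RISC. In mRNA of the same groups it averaged 2873 ± 62.8 CPM, 2585 ± 411 CPM, 2538 ± 165 CPM and 1891 ± 188 CPM. Ins1 averaged 8.68 ± 1.16 CPM (SD, n = 3) in ntg sham RISC, and its reads could not be assigned with certainty between Ins1 and Ins2.

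The atrial light chain Myl7 averaged 2.05 ± 0.852 CPM (SD, n = 3) in ntg sham, 24.3 ± 42.4 CPM (SD, n = 7) in TG133a sham, 424 ± 575 CPM (SD, n = 5) in ntg TAC and 40.5 ± 39.6 CPM (SD, n = 4) in TG133a TAC mRNA. In RISC the ntg sham mean was 86.0 ± 49.9 CPM (SD, n = 3). Mir133a-1 had reads in 3 transgenic RISC libraries, 10 in total, and Mir133b had 0 reads in all libraries.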
